A study of Homo sapiens with 6 samples.

How the data were processed

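RNA was measured in 6 samples of HCT116, an established human colorectal cancer cell line. Of these, 3 were the parental line (WT) and 3 were DKO1, a derivative of HCT116 described by the submitters as having the DNA methyltransferase genes DNMT1 and DNMT3B knocked out. Per the labels' protocols, both lines were grown in McCoy's 5A medium with foetal bovine serum, RNA was extracted with TRIzol, and stranded messenger RNA libraries were made with an Illumina kit and read on an Illumina HiSeq instrument. The labels number the replicates 1 to 3 in each group and do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

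The deposited values are TPM per gene, a transcript abundance corrected for gene length and scaled to the same total in every sample, which the authors rounded to 2 decimals. Per the submitters' processing notes, Trim Galore 0.4.0, FastQC, STAR 2.5.3a, RSEM 1.2.21 and edgeR 3.12.1 were used with builds hg19 and GRCh37. The notes give no role or order for these tools. The annotation release and whether counting used the strand are not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart with certainty. TPM has the same total in each sample and keeps no record of sequencing depth, so the depth of each sample is unknown, and no counting interval or detection floor is given. A listed 0 is an estimate of 0 or one below the rounding of the table.

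The table held 57897 rows, of which 57820 were human genes and 77 had names in the format of synthetic spike-in RNAs known as sequins. The labels do not mention spike-ins. These 77 rows held 1.28% to 2.01% of the TPM of a sample. They stayed out of every test of human genes and were examined on their own in a later part. Gene symbols, biotypes, chromosomes and the order of genes came from a reference gene table and GENCODE release 29 on GRCh38, matched by Ensembl identifier. A symbol was found for 52337 human rows (90.5%). Because this build differs from that of the submitters, no coordinates are given, and the reference served only for names, biotypes, chromosomes and which genes neighbour each other.

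The test was limma 3.58.1 in R 4.3.3, fitted to log2(TPM + 1) with a variance trend and genotype as the only term, for genes with at least 1 TPM in at least 3 of the 6 samples. The 13604 genes that passed were adjusted together by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. All log2 fold changes are DKO1 minus WT, with the standard error (SE) from limma. Where a group had a mean below 0.5 TPM no ratio of TPM is given, and genes at 0 in every sample of a group are described as listed at 0.

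The test, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The named genes are DNMT1, DNMT3B and DNMT3A, the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap, and up to 3 called members of each list with the largest change. Some results that this rule would name are not reported here. Pseudogenes, genes without an established symbol, Y-linked genes and XIST were not named. Of 27 gene lists, the 25 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, and again with a correlation estimated per list, and adjusted over the 25. The lists covered the DNA methylation machinery, X-linked cancer-testis antigens, germline and meiosis genes, genes with promoter methylation described in colorectal cancer, imprinted genes, interferon-stimulated genes, nucleic acid sensors, MHC class I presentation, endogenous retroviral genes, p53 targets, G2 and M phase genes, DNA replication, chromosome architecture, H3K9 and H3K27 methylation, Wnt targets, HOX genes, clustered protocadherins, cholesterol synthesis, hypoxia and glycolysis, the unfolded protein response, mitochondrially encoded genes and ribosomal proteins, and markers of epithelial, mesenchymal, intestinal, neural and blood cells. Shares of genes were compared with Fisher's exact test, two-sided, with 95% confidence intervals. Runs of neighbouring genes were tested by placing the called genes at random among the tested genes of each chromosome 10000 times.

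Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, no variance trend, the replicate number as a block, an estimated correlation for camera, and leaving out each sample in turn. Removing mitochondrial genes and spike-in rows and rescaling, leaving out neighbours with overlapping gene models, leaving the targeted genes out of the methylation machinery list, and the alternatives for the lincRNA class, the ZNF genes and chromosome 19 were added after the data were seen. Samples with the same replicate number deviated from their group means together, with correlations of 0.35, 0.57 and 0.27 over genes for numbers 1, 2 and 3. The numbers may therefore pair the samples. The fold changes, adjusted p-values and calls reported are from the fit without a block, unless the block is named. The fit with the block, planned beforehand, was run beside it. This pairing comes from the data, since the labels do not say that a number marks a shared day. No 2 samples had the values of a duplicated library, as at most 2.37% of genes had identical TPM in any pair.

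The procedure was tested on simulated data for DKO1 against WT over 13604 genes, with 200 genes changed by known amounts. The changed genes were drawn from those with a mean log2(TPM + 1) of at least 2, so the shares do not cover genes at lower levels. The share recovered was 8% at a log2 change of 0.5, 42% at 1, 86% at 2 and 100% at 3. Unchanged genes made up 7.1% of the simulated calls. The 200 changed genes are far fewer than the 3864 called in the data. The Benjamini-Hochberg cutoff is stricter when fewer genes change, so the recovered shares can understate those of the real fit. In simulated lists camera called 0 of 20 random lists, and random calls gave a mean ratio of observed to expected neighbour pairs of 1.01. Genes were simulated independently of each other, so the random lists cannot show how camera acts on correlated genes. The ratio for random calls checks only the calculation.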

Results

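Gene expression was compared between HCT116 cells and DKO1 cells, described by the submitters as the same colorectal cancer line with DNMT1 and DNMT3B knocked out, with 3 samples per genotype. All DKO1 samples are of 1 derived line and all WT samples of its parent. Effects of losing the 2 genes therefore cannot be told apart from other differences between these lines. DNMT1 copies DNA methylation to the new strand at replication and DNMT3B adds methylation to unmethylated sites. The series concerns how DNA methylation bears on the organisation of the genome, and its RNA part asks which transcripts differ between the 2 genotypes. More genes were detected in DKO1, with 13851.7 ± 547.2 genes at 1 TPM or above against 12287.3 ± 177.5 in WT (SD, n = 3, exact permutation p = 0.1, the smallest that 3 against 3 samples allow). Mitochondrially encoded transcripts took 26.9%, 27.7% and 21.2% of the TPM in DKO1 replicates 1, 2 and 3 and 19.8%, 19.7% and 20.1% in the WT replicates. Log2 values correlated at 0.988 to 0.992 between WT replicates, at 0.963 to 0.977 between DKO1 replicates and at 0.921 to 0.942 between genotypes, over genes. In what follows, values are mean TPM ± SD with n = 3 per genotype.

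The targeted genes were both lower in DKO1. DNMT1 (ENSG00000130816.10, chromosome 19) fell from 242 ± 9.81 TPM in WT to 36.2 ± 9.17 TPM in DKO1, 6.68-fold lower (log2 fold change −2.73, SE 0.17, adjusted p = 3.59e-05). DNMT3B (ENSG00000088305.14, chromosome 20) fell from 7.36 ± 0.76 to 4.42 ± 0.75 TPM (log2 fold change −0.63, SE 0.17, adjusted p = 0.03). DNMT3A, the methyltransferase that was not targeted, was at 2.36 ± 0.44 TPM in WT and 3.39 ± 0.32 TPM in DKO1 and did not pass (adjusted p = 0.11). The 3 DKO1 values of DNMT1 and of DNMT3B lay below all 3 WT values. A TPM value covers the whole gene, and transcripts of a disrupted allele still count, so these levels check the labels only in part. The DNMT3B call was lost without DKO1 replicate 1 (adjusted p = 0.0535) and without WT replicate 1, 2 or 3 (0.11, 0.0908 and 0.0778), and also with mitochondrial and spike-in rows left out and the rest rescaled (0.0645). In these fits its log2 fold change lay between −0.691 (without DKO1 replicate 1) and −0.555 (with the rescaling).

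**Figure D1:**
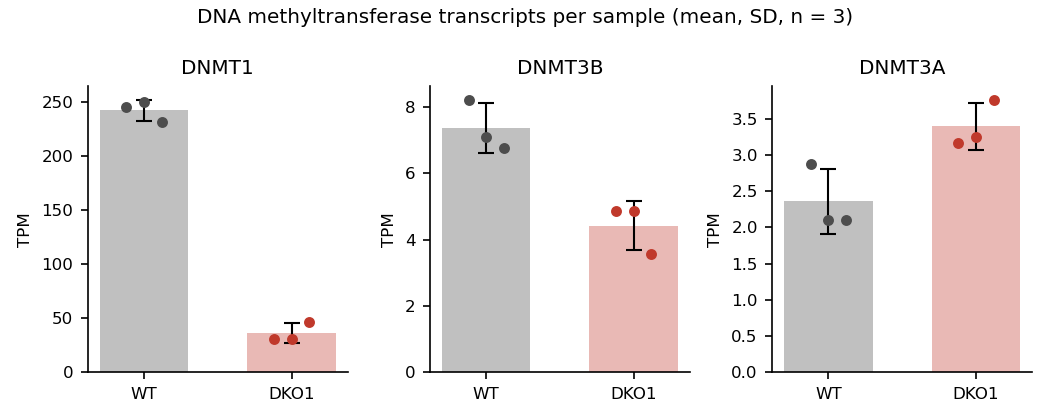
TPM of DNMT1, DNMT3B and DNMT3A in each sample. Points are samples, bars are means, error bars are SD (n = 3 per genotype), and each vertical axis starts at 0. DNMT1 falls from 242 to 36.2 TPM, and DNMT3B from 7.36 to 4.42 TPM.

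In the deposited scaling, rises outnumbered falls in DKO1. Of 13604 tested genes, 2558 rose and 1306 fell (66.2% of calls higher), and 1367 rose and 254 fell by at least 2-fold. Median-ratio scaling called 2293 higher and 1700 lower genes (57.4% higher). Quantile normalization called 1817 higher and 1939 lower genes (48.4% higher), with 856 higher and 520 lower by at least 2-fold, and it moved the median log2 fold change of all tested genes from 0.073 to −0.066. Quantile normalization gives every sample the same distribution of values, which pulls rises and falls toward balance, so it cannot decide whether rises were in excess. The leading rises were of genes that were close to silent in WT. UCHL1 (ENSG00000154277.8), a ubiquitin hydrolase of neurons and germ cells, went from 0.14 ± 0.12 to 238 ± 29.8 TPM (log2 fold change 7.71, SE 0.15, adjusted p = 1.64e-06). SOHLH2 (ENSG00000120669.11), a transcription factor of early germ cells, went from 0.22 ± 0.092 to 99.4 ± 4.05 TPM (log2 fold change 6.36, SE 0.14, adjusted p = 1.64e-06). CTCFL, the testis-specific relative of the insulator protein CTCF, rose from 0.52 ± 0.081 to 63.1 ± 2.28 TPM, and TDRD12, a factor of the piRNA pathway, rose from 0.31 ± 0.078 to 48.8 ± 7 TPM. C5orf58 reached 99.4 ± 23.1 TPM, the noncoding RNA OVAAL 64.3 ± 9.94 TPM, PAGE5 42.6 ± 5.81 TPM and the zinc finger gene ZNF266 34.7 ± 6.41 TPM in DKO1, each from a WT mean below 0.5 TPM. XAGE1B rose from 1.51 ± 0.74 to 347 ± 86.9 TPM, and GAGE12B was listed at 0 in WT and at 98.3 ± 74.4 TPM in DKO1. XAGE1B and GAGE12B have near-identical copies that can share reads, so the split among copies is uncertain.

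Among the largest falls, NR5A2 (ENSG00000116833.9), a nuclear receptor of gut and pancreas, fell from 44.3 ± 1.01 to 0.55 ± 0.23 TPM (log2 fold change −4.88, SE 0.16, adjusted p = 5.25e-06). KITLG (ENSG00000049130.9), the ligand of the KIT receptor, fell from 474 ± 23.7 to 27.7 ± 6.02 TPM, 17.1-fold lower (log2 fold change −4.07, SE 0.16, adjusted p = 7.54e-06). WNT16, a secreted WNT ligand, fell from 27.2 ± 0.47 to 0.67 ± 0.13 TPM, EREG, a ligand of the EGF receptor, from 21.5 ± 2.75 to 2.16 ± 0.43 TPM, and IL20RA, a cytokine receptor subunit, from 18.8 ± 1.26 to 0.65 ± 0.18 TPM. The kinase gene ALPK2 and the noncoding RNAs SFTA1P and LINC02331 also fell, with log2 fold changes of −4.13, −2.8 and −3.44. The small nucleolar RNA genes SNORA22B and SNORA2A were lower as well (log2 fold changes −3.15 and −2.85), but such short genes are poorly measured by messenger RNA libraries. Each of these lost its call in 5 of the 6 fits that leave out a sample, with an adjusted p from 0.0935 to 0.142 for SNORA22B and from 0.0552 to 0.103 for SNORA2A. Both calls were also lost with no filter (0.084 and 0.0604), and that of SNORA22B with a pseudocount of 0.1 (0.0586).

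The balance of rises and falls also depended on the level of the genes and on single samples. Among genes with a mean of at least 5 TPM, 1145 rose and 1077 fell (449 rose by at least 2-fold), and without a filter 4400 rose and 1098 fell. The number of lower genes was 2079 without DKO1 replicate 3, 842 without DKO1 replicate 1, and 604, 524 and 550 without WT replicate 1, 2 and 3, and the number of higher genes was 1705 without WT replicate 3. By at least 2-fold, 504 genes were lower without DKO1 replicate 3 and 159 without DKO1 replicate 1. The groups did not overlap for 6170 tested genes (45.4%), where chance gives 10%.

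**Figure D2:**
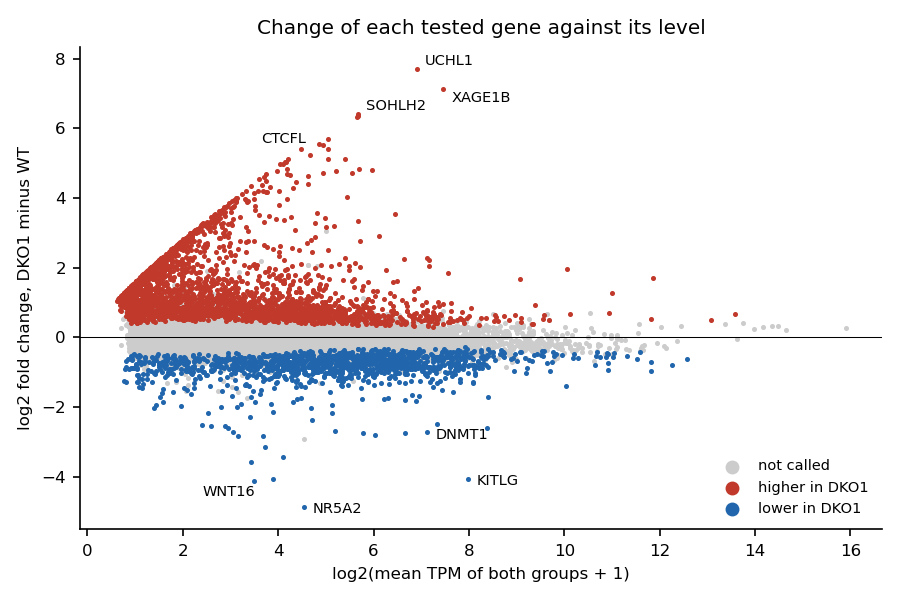
Log2 fold change of each tested gene (DKO1 minus WT, on the log2(TPM + 1) scale) against its mean level over both genotypes. Each point is a gene, red for the 2558 called higher, blue for the 1306 called lower and grey for the rest, and the largest rises, such as UCHL1 at 7.71, exceed the largest falls, such as NR5A2 at −4.88.

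Genes silent in WT and expressed in DKO1 were far more numerous than the converse. Counting genes below 0.1 TPM in every WT sample and at 1 TPM or above in every DKO1 sample gave 401, of which 280 were protein-coding, 37 lincRNAs, 17 antisense genes and 44 pseudogenes, and 40 reached at least 10 TPM. Among them were PAGE5, ZNF266, GREM1, TUSC3, NDN, CDH2, INA and HOXB2. The converse count was 3, namely PCDH7 (3.25 ± 0.47 TPM in WT), MAGEE1 (1.47 ± 0.2 TPM) and CIB4 (1.41 ± 0.18 TPM), which are named after their values were seen. This is a count with no test. The converse count was 5 without WT replicate 1 or DKO1 replicate 2 and 6 without WT replicate 2 or 3, and the larger count was 160 when WT values had to be exactly 0.

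The gene lists showed which kinds of genes moved. Of the 25 lists tested, 10 were called higher and 6 lower in DKO1 relative to other genes. With an estimated correlation 2 of the 16 calls held, those of the X-linked cancer-testis antigens and of the germline and meiosis genes. The imprinted, MHC class I and mesenchymal lists lost the call at estimates of 0.001, −0.016 and −0.024, below the preset 0.01. A correlation stronger than the preset therefore does not account for these losses, whose cause was not tested. The germline list, at an estimate of −0.023, kept its call but went from a camera adjusted p of 1.27e-10 to 0.0401. The form with an estimated correlation thus gave larger p-values even where the estimate lay below the preset. A call lost under it is therefore not by itself evidence that the genes of a list are correlated. The other lists that lost the call had estimates from 0.037 (neural) to 0.634 (ribosomal proteins). Genes silent in both genotypes were not tested, and a gene silent in WT entered only where it reached 1 TPM in DKO1, so shares and medians are those of tested members. A regrouping of the samples, WT replicates 1 and 2 with DKO1 replicate 3 against the rest, called 17 lists at the preset correlation. That regrouping still sets 2 samples of a genotype against 1, so it cannot tell genotype from other differences among samples. The number of lists called therefore does not by itself mark out genotype.

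Testis and germline genes rose together. Of 34 tested X-linked cancer-testis antigens, which are normally restricted to testis and expressed in some tumours, 28 rose and 0 fell (29 higher when adjusted over the list alone; median log2 fold change 2.04; camera adjusted p = 3.87e-15, and adjusted p = 0.0401 with an estimated correlation). MAGEA6 rose 36.9-fold, from 2.43 ± 0.26 to 89.5 ± 7.77 TPM, with XAGE1B and PAGE5 ahead of it. MAGE and XAGE family members share similar sequence, so single members are uncertain. Of 25 tested germline and meiosis genes, 20 rose and 0 fell (21 higher adjusted over the list alone; median 1.73; camera adjusted p = 1.27e-10, and adjusted p = 0.0401 with an estimated correlation), led by SOHLH2, CTCFL and TDRD12. The table held 62 of the antigens and 60 of the germline genes, and with no filter the medians were 1.075 and 0.543 with both calls kept (adjusted p = 9.89e-14 and 8.65e-11). A pseudocount of 0.1 gave medians of 3.301 and 3.439, and the germline median was 2.707 above a mean of 5 TPM.

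Interferon-stimulated genes rose nearly throughout. Of 38 tested members 33 rose, 1 fell and 4 did not pass (35 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 2 (3.023 with a pseudocount of 0.1; camera adjusted p = 1.86e-16, and adjusted p = 0.0629 with an estimated correlation). IFIT1, which binds viral RNA, rose from 3.3 ± 0.49 to 120 ± 8.4 TPM, 36.3-fold. MX2 rose from 0.083 ± 0.031 to 29.6 ± 7.01 TPM and IFI27 from 0.76 ± 0.27 to 46.8 ± 21.4 TPM. The member that fell was IFIT5, from 39.2 to 25.2 TPM, named after its value was seen. Of 10 tested sensors of double-stranded RNA and cytosolic DNA, 5 rose and 0 fell (5 higher and 1 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.056). The RNA sensors IFIH1 and RIGI rose 7.78-fold and 7.24-fold, and the DNA sensor IFI16 rose from 0.44 ± 0.23 to 5.37 ± 2.2 TPM. The sensor list was called without WT replicate 1 (adjusted p = 0.0406), under median-ratio scaling (0.046) and without a filter (0.00679). Antigen presentation by MHC class I rose in 15 of 19 members, with 1 lower (16 and 1 adjusted over the list alone; median 1.23; camera adjusted p = 6.31e-06, and adjusted p = 0.0546 with an estimated correlation). HLA-B rose 4.92-fold, from 46.8 ± 5.16 to 230 ± 18.2 TPM, and the immunoproteasome subunits PSMB8 and PSMB9 rose from 0.46 ± 0.19 to 13.8 ± 4.48 TPM and from 0.6 ± 0.22 to 6.86 ± 1.04 TPM. The lower member was the chaperone gene CANX, from 782 to 384 TPM, also named after its value was seen. HLA-B and its relatives are similar in sequence, so its level is uncertain. The list of endogenous retroviral genes with a symbol also holds genes named HHLA. Among its 5 tested members, 2 rose, of which 1 was HHLA3, and 1 fell, over all genes and over the list alone (camera adjusted p = 0.591). ERVK13-1 rose 2.61-fold, ERVMER34-1 fell 1.76-fold, and HHLA3 was at 13 ± 1.69 TPM in WT and 21.2 ± 5.16 TPM in DKO1 (adjusted p = 0.0433). The call of HHLA3 was lost without DKO1 replicate 1 (0.0944), without WT replicate 1, 2 or 3 (0.0857, 0.101 and 0.156) and under median-ratio scaling (0.0597) and quantile normalization (0.0814), and with no filter (0.0652).

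Genes known for promoter methylation rose in part. Of 31 tested genes described as methylated in colorectal cancer, 18 rose, 1 fell and 12 did not pass (20 higher and 3 lower adjusted over the list alone; median 0.93; camera adjusted p = 6.31e-06, and adjusted p = 0.15 with an estimated correlation). After UCHL1, the leading members were GREM1, a BMP antagonist, from 0.057 ± 0.031 to 32.5 ± 5.75 TPM, and TUSC3, from 0.053 ± 0.047 to 13 ± 0.73 TPM. The member that fell was DKK1, a secreted Wnt inhibitor, from 1527 ± 67.9 to 576 ± 69.4 TPM. Of 30 tested imprinted genes, 16 rose and 1 fell, PLAGL1 (17 higher and 3 lower adjusted over the list alone; median 0.55; camera adjusted p = 0.00202, and adjusted p = 0.0816 with an estimated correlation). PEG10 rose 20.1-fold, from 4.04 ± 0.38 to 81.3 ± 13.7 TPM, and NDN and MEG3 went from WT means below 0.1 TPM to 12.1 ± 3.61 and 10.6 ± 1.84 TPM. With no filter the medians of the promoter methylation and imprinted lists were 0.39 and 0.259, with both calls kept (adjusted p = 6.96e-06 and 0.00046). The promoter methylation median was 1.4 with a pseudocount of 0.1 and 0.569 above a mean of 5 TPM.

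HOX genes, which set position along the body axis, rose in most tested cases and fell in others. Of 26 tested HOX genes 16 rose and 5 fell (16 and 7 adjusted over the list alone; median 1.26; camera adjusted p = 0.00257, and adjusted p = 0.475 with an estimated correlation). All 9 tested HOXB genes rose, with HOXB9 from 1.59 ± 0.078 to 16.6 ± 3.49 TPM, HOXB8 from 0.14 ± 0.24 to 6.96 ± 0.72 TPM and HOXB2 from 0.023 ± 0.0058 to 6.2 ± 1.89 TPM. The 5 that fell, HOXA3, HOXA9, HOXA10, HOXA11 and HOXA13, all lie in the HOXA cluster; these 5 and the split by cluster were chosen after the values were seen. Under median-ratio scaling and under quantile normalization 8 of the 9 HOXB genes rose and 6 HOXA genes fell, and with mitochondrial and spike-in rows left out and the rest rescaled 9 HOXB genes rose and 3 HOXA genes fell. HOXA13 had a log2 fold change of −1.51 (adjusted p = 0.000735). The HOXA cluster had a median log2 fold change of −0.6, and of −0.64 under median-ratio scaling, −0.91 under quantile normalization and −0.54 with rescaling, against 2.07, 2.02, 1.75 and 2.36 for HOXB. The medians of HOXC and HOXD were 1.21 and 1.63, and under quantile normalization 0.504 and 1.36. The difference between clusters was not tested. For the whole HOX list the median was 0.426 with no filter and 0.664 under quantile normalization, with the call kept (adjusted p = 0.0102 and 0.00737). The 2 tested clustered protocadherins, PCDHB2 and PCDHGA10, both rose (both also adjusted over the list alone), to 1.28 ± 0.26 TPM from a listed 0 and from 0.52 ± 0.049 to 1.33 ± 0.059 TPM. Under quantile normalization the PCDHB2 call was lost (adjusted p = 0.168) and PCDHGA10 turned to a log2 fold change of −0.038, and without WT replicate 3 PCDHGA10 had an adjusted p of 0.0506.

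Lineage markers rose more often than they fell, as did all tested genes (2558 rose and 1306 fell). Of 12 tested neural genes 8 rose and 0 fell (10 higher adjusted over the list alone; median 1.71; camera adjusted p = 1e-06, and adjusted p = 0.0619 with an estimated correlation), among them INA, a neurofilament protein, from 0.02 ± 0.026 to 9.36 ± 2.78 TPM and STMN2 from 0.27 ± 0.051 to 9.67 ± 0.72 TPM. Of 12 tested mesenchymal genes 6 rose and 0 fell (7 higher adjusted over the list alone; median 0.98; camera adjusted p = 0.00179, and adjusted p = 0.0816 with an estimated correlation). CDH2, the neural cadherin, was listed at 0 in WT and at 10.8 ± 2.08 TPM in DKO1, and the collagens COL6A3 and COL6A1 rose 7.61-fold and 5.58-fold. With no filter the neural and mesenchymal medians were 0.646 and 0.416 with both calls kept (adjusted p = 2.31e-07 and 7.32e-05), and the mesenchymal median was 1.53 above a mean of 5 TPM. Of 24 tested epithelial genes 8 rose and 0 fell (8 higher and 1 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.16). KRT7 rose from 0.6 ± 0.18 to 20.1 ± 7.38 TPM, and KRT23 and ELF3 rose 7.51-fold and 9.41-fold. Of 6 tested blood and immune genes 3 rose and 0 fell (4 higher and 1 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.0835), except without WT replicate 2 (0.0492) and without a filter (0.0495). The T cell receptor component CD3D rose from 0.14 ± 0.16 to 5.68 ± 1.16 TPM, LYZ from 0.087 ± 0.081 to 2.37 ± 0.12 TPM and HLA-DRA 2.91-fold, although HLA-DRA lost its call under quantile normalization (adjusted p = 0.0688). Of 3 tested intestinal genes 1 rose, TFF2, from 0.087 ± 0.15 to 15.3 ± 3.95 TPM, and 1 fell, the transcription factor CDX2, from 1.31 ± 0.081 to 0.64 ± 0.11 TPM (both also adjusted over the list alone). The CDX2 call was lost without WT replicate 1, 2 or 3 (adjusted p = 0.0953, 0.0789 and 0.102).

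**Figure D3:**
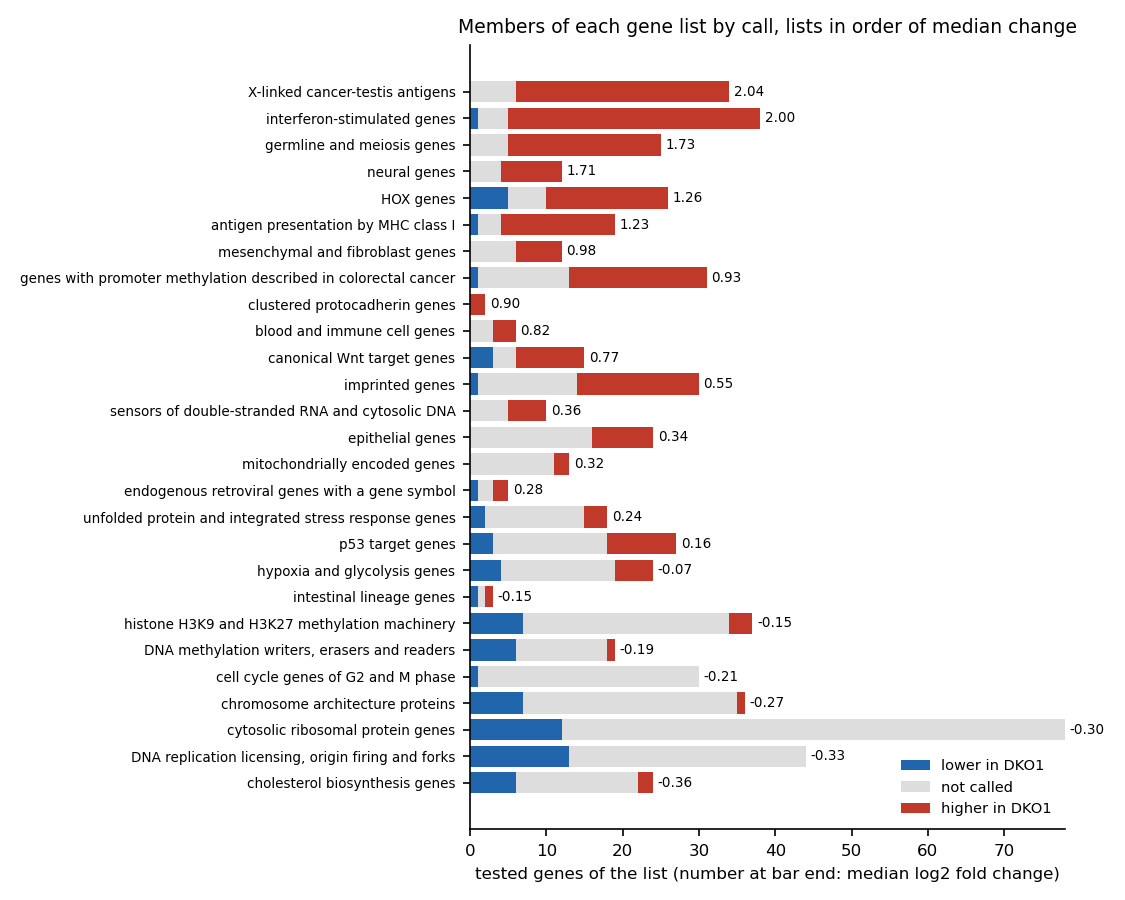
Tested members of each of the 27 gene lists, as horizontal bars split into genes called lower (blue), not called (grey) and called higher (red) in DKO1, with the median log2 fold change at the end of the bar. Lists run from X-linked cancer-testis antigens, with 28 of 34 higher, at the top to cholesterol biosynthesis genes, with 6 of 24 lower, at the bottom.

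Lists of chromatin and DNA replication genes were lower. Of 44 tested replication genes 13 fell and 0 rose, over all genes and adjusted over the list alone (median −0.33; camera adjusted p = 4.65e-05, and adjusted p = 0.325 with an estimated correlation). POLA1, the catalytic subunit of DNA polymerase alpha, fell from 34.7 ± 1.16 to 19.2 ± 3.17 TPM, RFC1 fell from 117 ± 10.7 to 69 ± 21.1 TPM, and RIF1, a regulator of replication timing, fell from 60.2 ± 6.17 to 29.7 ± 14.7 TPM (adjusted p = 0.0352). Of 36 tested chromosome architecture genes 7 fell and 1 rose (6 and 1 adjusted over the list alone; median −0.27; camera adjusted p = 0.00257, and adjusted p = 0.513 with an estimated correlation). The cohesin subunit STAG2 fell from 80.7 ± 3.34 to 34.8 ± 12.9 TPM and SMCHD1 from 62.5 ± 8.2 to 34.3 ± 12.3 TPM, while SATB1 rose from 0.14 ± 0.09 to 5.12 ± 0.078 TPM. Of 37 tested genes of H3K9 and H3K27 methylation 7 fell and 3 rose, also when adjusted over the list alone (median −0.15; camera adjusted p = 0.0253, and adjusted p = 0.513 with an estimated correlation). SUZ12 of the Polycomb complex, CBX3 and TASOR of the HUSH complex fell 1.83-fold, 1.8-fold and 1.85-fold. Of 19 tested genes of the DNA methylation machinery 6 fell and 1 rose, also when adjusted over the list alone (median −0.19; camera adjusted p = 0.0185, and adjusted p = 0.513 with an estimated correlation). The list holds both targeted genes, so part of its count is set by the design. Without them 4 of 17 fell and 1 rose, and the list was not called (median −0.154; camera adjusted p = 0.0852, and adjusted p = 0.572 with an estimated correlation). Besides the targeted pair, TET1, which oxidises methylcytosine, fell from 1.55 ± 0.092 to 0.5 ± 0.13 TPM and the methyl-CpG binding gene MBD1 rose 1.89-fold.

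These falls differed among the DKO1 samples. In DKO1 replicates 1, 2 and 3, RIF1 stood at 17.7, 25.4 and 46.1 TPM, STAG2 at 24.7, 30.3 and 49.3 TPM and SUZ12 at 37.9, 54 and 69.7 TPM, and replicate 3 was also the DKO1 sample with the lowest mitochondrial share, 21.2%. Leaving out 1 sample ended the calls of RIF1 (5 of 6 samples, adjusted p from 0.0712 to 0.117), SMCHD1 (5, from 0.0564 to 0.12), TASOR (5, from 0.0513 to 0.091), RFC1 (3, from 0.0802 to 0.116), SUZ12 (3, from 0.0532 to 0.0645) and CBX3 (2, from 0.0649 to 0.0699). The log2 fold change of RIF1, −1.096 with all samples, was −1.181, −1.069 and −1.039 without WT replicate 1, 2 and 3. It was −0.793 without DKO1 replicate 1 and −1.039 without DKO1 replicate 2. That of SUZ12, −0.903 with all samples, was −0.937, −0.847 and −0.926 without WT replicate 1, 2 and 3. With no filter the calls of RIF1, RFC1 and SMCHD1 were lost as well (adjusted p = 0.0689, 0.0694 and 0.0707). Under quantile normalization the calls of the methylation machinery, architecture and H3K9 and H3K27 lists were lost (adjusted p = 0.058, 0.0991 and 0.0935), and that of the replication list was kept (0.0488). With mitochondrial and spike-in rows left out and the rest rescaled, the median of all tested genes was 0.173, against 0.073 as deposited. In that rescaling the medians were −0.219 for replication, −0.159 for architecture, −0.044 for H3K9 and H3K27 and −0.086 for methylation machinery, and all of these calls were kept (adjusted p = 9.36e-05, 0.00303, 0.0288 and 0.0162). The methylation machinery median was −0.121 without DKO1 replicate 1, −0.355 without DKO1 replicate 3 and −0.39 above a mean of 5 TPM. That of the H3K9 and H3K27 list was −0.097 without WT replicate 1 and −0.083 and −0.087 without DKO1 replicates 1 and 2.

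Of 78 tested ribosomal protein genes 12 fell and 0 rose (4 lower adjusted over the list alone; median −0.3; camera adjusted p = 8.58e-07, and adjusted p = 0.513 with an estimated correlation). RPL7 fell from 6144 ± 181 to 3586 ± 605 TPM, RPL26 from 4478 ± 404 to 2795 ± 622 TPM and RPS27A from 3572 ± 177 to 2315 ± 296 TPM. RPL26 lost its call without DKO1 replicate 1 or any 1 WT replicate (adjusted p from 0.0553 to 0.107) and with no filter (0.0638), RPS27A lost it without WT replicate 3 (0.0609), and the list was not called under quantile normalization (0.0624). The median of the list was −0.066 without DKO1 replicate 2, −0.463 without DKO1 replicate 3 and −0.187 with the rescaling, with the call kept in each. Ribosomal protein genes have many processed copies, which adds uncertainty to single members. Of 13 mitochondrially encoded genes 2 rose and 0 fell (0 adjusted over the list alone), and the list was not called (median 0.32; camera adjusted p = 0.0835), but was called with the replicate number as a block (0.0404), without DKO1 replicate 3 (0.0118) and above a mean of 5 TPM (0.00493). MT-ND3 rose from 9345 ± 459 to 15160 ± 2693 TPM and MT-ND5 from 2930 ± 170 to 4290 ± 685 TPM, and both calls were lost without DKO1 replicate 1 or any 1 WT replicate (adjusted p from 0.0672 to 0.109 for MT-ND3) and, for MT-ND5, also without DKO1 replicate 2 (0.0646 to 0.126), and under median-ratio scaling (0.067 and 0.109) and with no filter (0.0715 and 0.0756).

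Signalling and metabolic lists were mixed. Of 15 tested Wnt targets 9 rose and 3 fell, also when adjusted over the list alone (median 0.77; camera adjusted p = 0.0386, and adjusted p = 0.475 with an estimated correlation). BAMBI rose from 0.42 ± 0.15 to 5.36 ± 1.64 TPM and the transcription factor SOX9 4.31-fold, while DKK1, MYC and TCF7L2 fell, the last 2 named after their values were seen. This list lost its call with the replicate block (adjusted p = 0.0523), without WT replicate 3, DKO1 replicate 1 or DKO1 replicate 2 (0.0536, 0.065 and 0.104), under quantile normalization (0.0991), with the rescaling (0.0562) and above a mean of 5 TPM (0.558), and its median was 0.48 with no filter (0.022). Of 24 tested cholesterol synthesis genes 6 fell and 2 rose, also when adjusted over the list alone (median −0.36; camera adjusted p = 0.0114, adjusted p = 0.44 with an estimated correlation and 0.0944 under quantile normalization). The median was −0.197 without DKO1 replicate 2 (adjusted p = 0.0349). SQLE, an enzyme of the pathway, rose 7.89-fold and TM7SF2 from 0.75 ± 0.2 to 3.02 ± 1.27 TPM. TM7SF2 lost its call without DKO1 replicate 1, WT replicate 2 or WT replicate 3 (adjusted p = 0.0532, 0.0585 and 0.0502) and under quantile normalization (0.0541). Of 27 tested p53 targets 9 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.192, and 0.0258 above a mean of 5 TPM), with SERPINB5, TP53I3 and the cell cycle inhibitor CDKN1A up 8.06-fold, 3.65-fold and 3.84-fold. Of 24 tested hypoxia and glycolysis genes 5 rose and 4 fell, also over the list alone, with a median of −0.068, a mean of 0.17 and a camera direction of lower (adjusted p = 0.613), which turns to higher under quantile normalization (0.659). SLC2A3, NDRG1 and BNIP3L rose 7.61-fold, 5.14-fold and 2.88-fold. Of 18 tested stress response genes 3 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.605), with ATF3 and DDIT3 up 2.43-fold and 2.26-fold and PSAT1 down 1.79-fold. Of 30 tested G2 and M phase genes 1 fell, the checkpoint kinase BUB1, from 113 ± 10.9 to 59.1 ± 9.02 TPM, and 0 rose, also over the list alone. The G2 and M list was not called (median −0.21; camera adjusted p = 0.104), was called lower without DKO1 replicate 3 (0.0191), under median-ratio scaling (0.0479) and without a filter (0.0102), and had a camera direction of higher under quantile normalization (0.837).

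**Figure D4:**
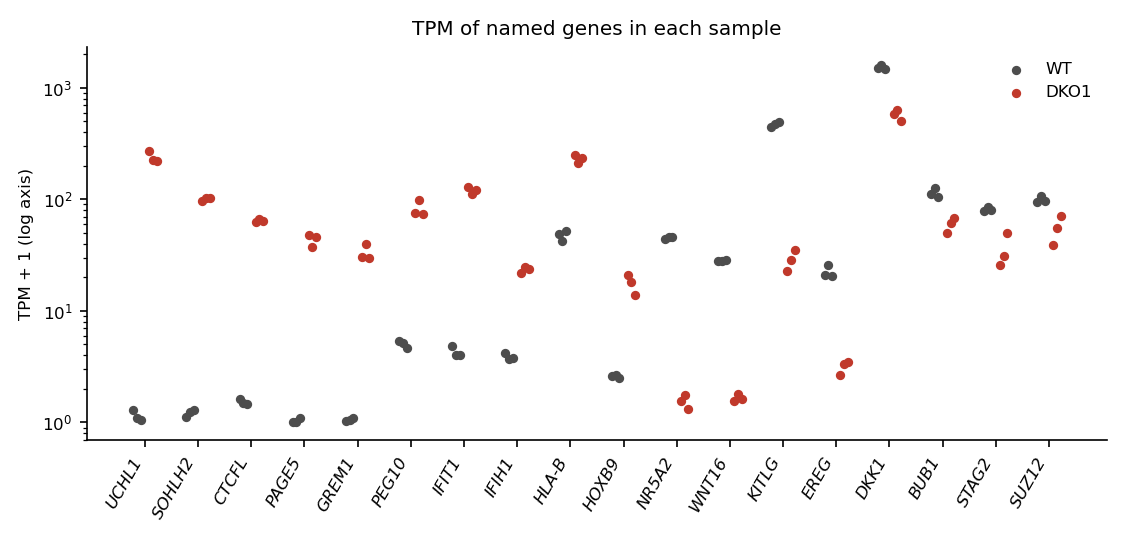
TPM plus 1, on a log axis, of 18 named genes in each sample, grey for WT and red for DKO1. The 3 samples of a genotype lie apart from those of the other for each gene, as for IFIT1 (3.3 against 120 TPM) and KITLG (474 against 27.7 TPM).

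Rises were compared between X and the autosomes because many cancer-testis antigens are X-linked. Of 451 tested X-linked genes 60 rose by at least 2-fold (13.3%), against 1260 of 12756 autosomal genes (9.88%; odds ratio 1.4, 95% interval 1.04 to 1.85, Fisher's exact p = 0.0204). Without the cancer-testis list, 34 of 417 X-linked genes rose by at least 2-fold (8.15%), and the odds ratio was 0.81 (0.55 to 1.16, Fisher's exact p = 0.277). Genes are not independent replicates. The call was lost without DKO1 replicate 2 (odds ratio 1.18, Fisher's exact p = 0.25), with a pseudocount of 0.1 (1.298, p = 0.0592), with no filter (1.273, p = 0.0686) and with mitochondrial and spike-in rows left out and the rest rescaled (1.275, p = 0.0866).

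Rises by at least 2-fold lay next to each other more often than chance placement gives. Among 13184 adjacent pairs of tested genes, 354 had both members higher, against 135.9 expected (2.6 times, permutation p = 1e-04, the smallest that 10000 random placements can give). With pairs whose symbols share leading letters and pairs with a gene without a symbol left out, 221 pairs remained against 124.9 (1.77 times, permutation p = 1e-04). The longest run held 13 genes on chromosome 17, from SKAP1 through HOXB2 to HOXB9 and on to PRAC1, and a run on chromosome 6 held PSMB8, PSMB9, TAP1 and HLA-DMB. Genes lower by at least 2-fold also adjoined, with 24 pairs against 5.5 expected (4.4 times, permutation p = 1e-04). For these falls no count was made without similar or overlapping genes, so reads shared between such genes can add to the ratio.

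**Figure D5:**
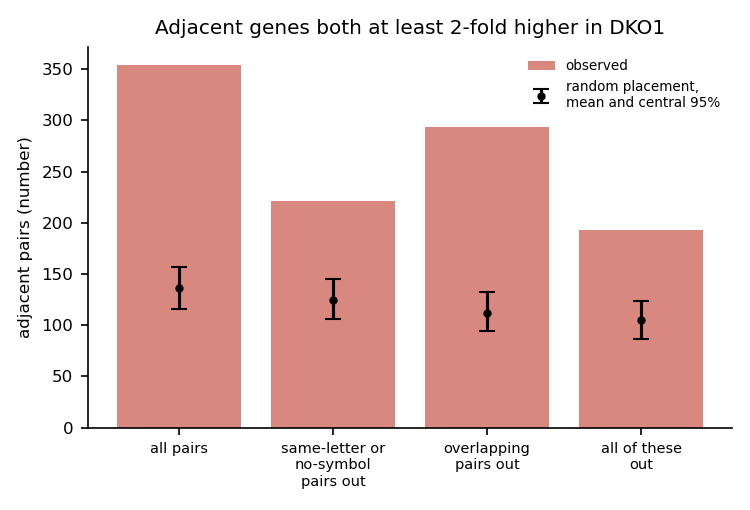
Adjacent pairs of tested genes that both rose by at least 2-fold in DKO1, for all pairs and with pairs of same-letter or missing symbols, pairs with overlapping gene models, or all of these left out. Bars are observed pairs (354, 221, 294 and 193), and points with bars are the mean and central 95% of 10000 random placements (means of 135.9, 124.9, 112.4 and 105).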

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

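All tests of the spike-in rows in this part were chosen after their values were seen. Outside the human genes, 44 of the 77 rows with names in the format of sequins had a mean of at least 1 TPM, a signal in rows that no comparison used. Of these 44 rows, 7 were higher and 9 lower in DKO1 than in WT by at least 2-fold with the groups apart, and the other 28 had a median log2 fold change of 0.11. Log2 fold changes over the rows ran from −3.68 to 4.84. Noise at low levels is argued against, since 4 of 13 rows of at least 100 TPM differed by at least 2-fold with the groups apart. A difference of spike-in mixture between the genotypes is consistent with the 10 rows of at least 10 TPM that differed in this way, 6 higher and 4 lower, since sequins are made in mixtures that hold the same RNAs at different levels. It stays open, because the labels name no mixture, and no biological explanation was tested.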

How the results depend on the processing

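Across the alternatives 410 of 476 summary values kept their direction and their side of the threshold, 31 lost a call, 12 gained one, 20 counts moved by over 1.5 times and 3 turned direction. The rescaling without mitochondrial and spike-in rows, the removal of overlapping neighbours, the methylation list without the targeted genes and the alternatives for the lincRNA class, the ZNF genes and chromosome 19 were chosen after seeing the data. Of 1239 values under alternatives of the 90 called genes that the naming rule picks, 1158 kept their call, 80 lost it and 1 reversed, the gene PCDHGA10 at −0.038 under quantile normalization. The excess of neighbouring pairs was kept in each alternative run. Depth is unknown, so its limits could not be set. Except where fewer genes or samples entered the fit, the cause of a change was not tested.

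Genes higher in DKO1 numbered 4400 with no filter and 1145 above a mean of 5 TPM (449 by at least 2-fold), and quantile normalization gave 856 higher and 520 lower by at least 2-fold. Leaving out each sample gave 1705 (without WT replicate 3) to 2842 higher genes, 524 (without WT replicate 2) to 2079 lower genes (without DKO1 replicate 3) and 159 (without DKO1 replicate 1) to 504 lower by at least 2-fold (without DKO1 replicate 3). Requiring exactly 0 TPM gave 160 genes silent in WT and 1 in the converse, which was 7 with limits of 0.05 and 0.5 TPM and 3 to 6 when leaving out a sample.

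With an estimated correlation the calls of 14 lists were lost at the same medians, 0.927 for genes with promoter methylation, 0.549 for imprinted, 1.997 for interferon-stimulated, 1.23 for MHC class I, 0.98 for mesenchymal, 1.706 for neural, 1.258 for HOX, 0.766 for Wnt, −0.194 for methylation machinery, −0.329 for replication, −0.269 for architecture, −0.154 for H3K9 and H3K27, −0.36 for cholesterol and −0.299 for ribosomal genes. Under quantile normalization the lower lists lost their calls at medians of −0.392 (methylation machinery), −0.206 (architecture), −0.15 (H3K9 and H3K27, and ribosomal) and −0.328 (cholesterol), with replication as the exception. Quantile normalization also turned the test direction for G2 and M genes (median −0.085) and hypoxia genes (−0.059). Without the targeted genes the methylation machinery list lost its call (median −0.154, adjusted p = 0.0852, from 0.000961 to 0.0852 over its alternatives with the preset correlation).

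With the replicate block the Wnt list lost its call (median 0.766, adjusted p = 0.0523) and the mitochondrial list gained one (0.318, adjusted p = 0.0404). The block changed no other list call and not the calls for X or for neighbouring pairs. It called 3053 higher and 1817 lower genes, with 3835 of the 3864 genes called without it among them. The Wnt list also lost it above a mean of 5 TPM (0.204), under quantile normalization (0.151) and with rescaling (0.941), and leaving out a sample gave medians of 0.727 to 0.859, with adjusted p from 0.0179 to 0.558 over alternatives. Calls were gained by the sensors with no filter (0.353), median-ratio scaling (0.307) and without WT replicate 1 (medians 0.327 to 0.536 over samples left out), by p53 targets above 5 TPM (0.403), by G2 and M genes with no filter (−0.209), median-ratio scaling (−0.278) and without DKO1 replicate 3 (medians −0.412 to −0.083 over samples left out), by blood genes with no filter (0.223) and without WT replicate 2 (medians 0.722 to 0.935 over samples left out) and by mitochondrial genes above 5 TPM (0.318) and without DKO1 replicate 3 (medians 0.244 to 0.461 over samples left out).

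The call for X against autosomes was lost with a pseudocount of 0.1 (odds ratio 1.298), with no filter (1.273), with rescaling (1.275) and without DKO1 replicate 2 (1.183), and the direction turned without the cancer-testis list (0.81). Leaving out a sample gave odds ratios of 1.183 to 1.448, with p from 0.0111 to 0.277 over alternatives. The odds ratio of rises by at least 2-fold among lincRNAs against other tested genes turned from 2.99 to 0.77 with no filter, which brought the tested lincRNAs from 436 to 2990, and lay above 1 in the other alternatives. That of falls turned from 1.79 to 0.53 with no filter and was 0.99 without DKO1 replicate 3. The excess of rises among ZNF genes on 19, against other genes on 19 and against ZNF genes elsewhere, and that of chromosome 19 kept their direction and call in each alternative run.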

Other observations

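The classes and chromosomes in this part with their alternatives, the test of neighbouring pairs without overlapping or similar genes and the window that includes pair members were chosen after the results were seen; the other tests were set down before their values were seen. Rises in DKO1 were more frequent among lincRNAs than among other genes that passed the filter. Of 436 tested lincRNAs 105 rose by at least 2-fold (24.1%; odds ratio against other genes 2.99, 95% interval 2.36 to 3.77, Fisher's exact adjusted p = 2.46e-17), against 1043 of 11347 protein-coding genes (9.2%), and 14 fell by at least 2-fold (3.2%), against 217 protein-coding genes (1.9%). Above a mean of 5 TPM 20 of 100 lincRNAs rose and 11 fell by at least 2-fold, with odds ratios against other genes of 4.96 and 5.67 (Fisher's exact p = 7.17e-08 and 1.3e-05), and quantile normalization gave 52 higher and 40 lower (2.08 and 2.67, p = 7.78e-06 and 2.94e-07). With no filter 120 of 2990 lincRNAs rose (4%), a smaller share than of other genes (odds ratio 0.77, Fisher's exact p = 0.00549), so the excess was seen only among lincRNAs that passed a filter on level. The odds ratio for falls was 1.79 (Fisher's exact p = 0.0455) and turned to 0.53 with no filter (p = 0.0267). It lost its call under median-ratio scaling (1.35, Fisher's exact p = 0.265) and without WT replicate 3, DKO1 replicate 2 or DKO1 replicate 3 (1.64, 1.73 and 0.99). Antisense genes rose by at least 2-fold in 55 of 419 cases (13.1%) and pseudogenes in 87 of 702 (12.4%), and the level of either can include reads of an overlapping or similar gene.

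Among chromosomes, 19 was the one with more rises that passed, with 117 of 779 tested genes higher by at least 2-fold (15%; odds ratio 1.64, Fisher's exact adjusted p = 0.000155 over 23 chromosomes). On 21 the share was higher in a smaller set, 23 of 131 genes (17.6%; odds ratio 1.92), and did not pass (adjusted p = 0.0596). The excess on 19 lay in genes named ZNF, most of which encode zinc finger transcription factors. On 19, 81 of 188 ZNF genes rose by at least 2-fold (43.1%), against 36 of 591 other genes on 19 (6.1%; odds ratio 11.6, 95% interval 7.33 to 18.7, Fisher's exact p = 4.24e-30) and 25 of 224 ZNF genes on other chromosomes (11.2%; odds ratio 6, 3.55 to 10.4, p = 1.15e-13). Of the 81, 68 had a WT mean below 1 TPM and so entered the test only through their DKO1 level. With no filter 88 of 287 ZNF genes on 19 rose by at least 2-fold (30.7%), against 44 of 1442 other genes on 19 (3.1%; odds ratio 14, Fisher's exact p = 5.44e-42) and 30 of 312 ZNF genes elsewhere (9.6%; odds ratio 4.15, p = 8.1e-11). The odds ratio against other genes on 19 was 6.73 above a mean of 5 TPM (Fisher's exact p = 3.78e-07) and 7.21 without DKO1 replicate 2 (p = 8.25e-23). Several of the longest runs were ZNF clusters on 19, with 9 genes from ZNF260 to ZNF585A and 9 from ZNF772 to ZNF134, and other runs held MAGEA genes on X (8 genes) and S100 genes on 1 (4 genes in each of 2 runs).

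For the ZNF genes on 19, copy number gain shared by most of their clusters is argued against. The 69 other genes on 19 within 5 positions of a called ZNF gene had a median log2 fold change of 0.098 relative to all tested genes (95% bootstrap interval −0.027 to 0.215), while the 81 called ZNF genes had a median of 2.04. Every gene whose symbol starts with Z was left out of the 69. This also removed risen neighbours not named ZNF, such as ZIK1 and ZSCAN18, which can lower the median. Scaling between samples is also argued against, with an odds ratio of 12.69 against other genes on 19 under quantile normalization (7.44 to 22.3, 64 ZNF genes higher). Reads of a few risen genes assigned to similar genes stay open: the 3 genes that gained most held 14.4% of the 471.9 TPM gained, and the low share set down beforehand as evidence against this excludes nothing, since spreading reads over similar genes lowers it too. A candidate explanation is release of ZNF promoters by loss of DNA methylation, which was not tested here because the methylation data of the study are not used here.

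For the runs of neighbouring genes, reads shared between overlapping or similar genes are argued against as the whole cause, since with such pairs and those with a gene without a symbol left out the ratio was 1.84 (193 pairs against 105 expected, of which random placement gives at most 124 at the upper 95% bound). Regional copy number gain is argued against only as a cause shared by most of the pairs. The 1864 tested genes within 5 positions of the pairs had a median log2 fold change of 0.004 relative to all tested genes (95% bootstrap interval −0.026 to 0.029). This value is lowered by selection, since a called gene next to a pair member is itself a pair member and was left out. With the 571 pair members included, at a median of 1.75 themselves, the median was 0.19 (0.153 to 0.235). A median pooled over all regions cannot exclude copy number gain in some of them. No test here bears on shared regulation of neighbours after loss of methylation, which stays open.

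The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Called genes numbered 3864 in the real split and at most 1 in another, so that 1 of the 10 splits gave as many. By at least 2-fold the numbers were 1621 and 1, again with 1 of the 10. Every other split mixes the genotypes in both groups, so the difference between genotypes widens the spread within groups. Few called genes were therefore due in those splits beforehand, and their numbers do not measure what chance gives. For gene lists 3 of the 10 splits gave at least the 16 lists called, and the highest other, WT replicates 1 and 2 with DKO1 replicate 3 against the rest, gave 17. This split parts all 3 replicate pairs, as 4 of the 10 do with the real split included, and it sets DKO1 replicates 1 and 2 with WT replicate 3. Besides it and the real split, the splits that part all pairs gave 9 and 6 lists. DKO1 replicate 3 with WT replicates 2 and 3 against the rest gave 16 lists, and with WT replicates 1 and 3 it gave 14. The splits that set DKO1 replicate 3 with 2 WT samples thus gave 14 to 17 lists. The remaining splits, without the real one, gave 3 to 9. Each split other than the real one sets 2 samples of a genotype against 1, so genotype enters its list calls too. The 17 lists therefore cannot tell genotype from another structure among the samples.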
